A study of Homo sapiens with 2 samples.

How the data were processed

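Total RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. How RNA was selected before sequencing is not given in the sources used here. SV-HUC-1 cells were infected for 48 h with lentivirus carrying a scrambled or an AP-2α shRNA and selected with puromycin at 1 µg/mL, per the series' design text. There were 2 libraries, 1 per group, and the labels of each name its shRNA. How many cultures went into each library is not given in the sources used here.

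TopHat2, an aligner, Cufflinks, a transcript quantifier, and the genome build GRCh37 are named in the submitters' processing notes, without versions. Which counting rule was used, whether strand was considered and how multiply mapped reads were treated are not given in the sources used here. Genes that overlap another gene or share sequence with a near-identical copy are therefore uncertain. Each library's file holds, per the file headers, a count per gene, an FPKM value, a further normalized value, and the gene's length and position. The deposited counts are whole numbers with different totals in the 2 libraries and were taken as unnormalized counts. The FPKM values, which correct for gene length and depth, were computed by the authors, and the effective lengths behind them are not given. The normalized column is a signal of scaled counts made by the authors: its ratio to the count was nearly the same for every gene of a library, with medians of 1.16 in the control and 0.864 in the knockdown library. A further 2 tables of the whole series, with 4 columns of per-sample values, were not used because their column names match no sample label.

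The tables list 20782 features, of which 20036 have Ensembl identifiers and 746 are unannotated loci numbered by the authors. The unannotated loci took 0.607% of control counts and 0.719% of knockdown counts and were kept. Gene symbols were taken by identifier from a table of current gene names for 18778 features, and from GENCODE v29 for 24 more. The other 1234 Ensembl identifiers were left without a symbol. Older symbols in the gene lists were matched through RefSeq synonyms when they led to a single gene. Coordinates are those of the files, in GRCh37; GENCODE v29 is built on GRCh38 and was used only for names, gene types and GC content. The tables hold 0 features of the mitochondrial genome, so that list was not analysed here.

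Counts were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, which gave effective library sizes of 19234153 for the control and 25083222 for the knockdown library. On the CPM scale, a count of 1 corresponded to 0.0520 and 0.0399. The 10 most abundant genes took 4.72% and 5.16% of counts. A gene was called measured with at least 50 counts over both libraries and an FPKM of at least 1 in either. The ratio is the knockdown over the control level, with no added count, and no measured gene was at 0 in a library. The 95% interval is the exact Clopper-Pearson interval of the knockdown library's share of the gene's counts, computed with SciPy 1.17.1. It covers counting error only and not the spread between cultures, so it understates the true error. A count of 0 was taken to allow up to 3 counts.

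No test between conditions was made because each group had 1 library. Genes were described by a rule of size, at least 2-fold in either direction. For 37 gene lists, the median log2 ratio of measured members was given with an exact binomial interval from order statistics. It was also given as a percentile among 10000 random lists of the same size, drawn with replacement from measured genes in the same of 20 bins of mean expression (0.5 counts added for the binning). The percentile was computed for the 35 lists with at least 3 measured members. The lists covered the AP-2 family, AP-2 partners, reported AP-2α targets, epithelial and mesenchymal states, signalling, stress and metabolic pathways, cell cycle, RNA quality and other cell types. The gene lists, the size rule, the rule for named genes and the alternatives below, apart from those named as added, were fixed before the data were examined.

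Named genes were the AP-2 family and the 15 measured genes with the largest ratio in each direction, with at least 100 counts and an FPKM of at least 2 in the higher library, leaving out features with no symbol and, by the start of their symbol, clone names and small RNAs. To these were added the 4 members with the largest ratio in the direction of the median for each list below percentile 2.5 or above percentile 97.5, and up to 4 members of at least 2-fold for the other lists. Some genes that this rule or the closing section would name are not reported here.

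The procedure was tested on simulated counts for this comparison, drawn from the real means and library sizes with 200 genes changed. Over the 12895 simulated genes with at least 50 counts, 95.4% of the intervals held the true ratio. All 50 genes changed 3-fold passed the 2-fold rule (100%), none of those changed 1.5-fold did, and 0.0315% of unchanged genes did. Of 200 random lists of 20 genes, 5.50% fell outside the central 95%, and a list of 20 genes raised 3-fold lay at percentile 100. The random lists came from the same simulated genes as their reference lists, so a share near the nominal one was built in. These simulations hold counting noise, no variation between cultures and no pathway genes that vary together.

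Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile scaling, ratios of the deposited FPKM values with pseudocounts of 0.1 and 1, other filters and size rules, means in place of medians, and removal of a length trend. Ratios from the authors' scaled counts and removal of trends on expression, GC content and length together, and other scalings for the medians by expression decile, were added after the data were seen. GC content was available for 94.8% of measured genes. Smooth trends were fitted with statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.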

Results

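RNA sequencing was used to compare SV-HUC-1 cells carrying a lentiviral shRNA against AP-2α with cells carrying a scrambled shRNA. SV-HUC-1 is an immortalised human urothelial cell line, and the labels describe it as bladder cells. AP-2α, the product of TFAP2A, is a sequence-specific transcription factor of epithelial and neural crest lineages. The comparison describes which genes differed in RNA level between the 2 libraries. It cannot separate AP-2α loss from other effects of the shRNA or from differences between the cultures. Each arm had 1 library, so the data hold no replicates, no difference could be tested against a spread between samples, and no p-value is given. The scrambled shRNA library held 19915476 counts over genes and the AP-2α shRNA library held 24225107. At least 1 count was found for 16273 and 16416 genes, respectively. Intervals beside the fold or ratio of a single gene are exact 95% intervals that cover counting error only. Those beside the median of a list are 95% binomial intervals from order statistics of its members' ratios. They treat the members as independent, and neither kind covers the spread between cultures.

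TFAP2A RNA was lower in the knockdown library. The gene (ENSG00000137203, minus strand of chromosome 6, 10393419 to 10419892 in GRCh37) had 5281 counts and an FPKM of 159 in the control library, against 2631 counts and an FPKM of 51.3 in the knockdown library. After scaling this was a 2.62-fold lower level, a ratio of 0.382 with an interval of 0.364 to 0.400. The paralogue TFAP2C was 1.23-fold lower (interval 1.10 to 1.38), with FPKM values of 13.8 and 10.4. TFAP2E was near the limit of measurement, with 25 and 32 counts and a fold of 1.02 whose interval of 0.579 to 1.77 included no difference. TFAP2B and TFAP2D had 0 counts in each library, which allows up to 3 counts, or 0.156 CPM in the control library and 0.120 CPM in the knockdown library. Among 9 measured coactivators and partners of AP-2 proteins, 1 differed by at least 2-fold: CITED2, a CBP/p300-binding coactivator, was 2.40-fold higher. The median of that list lay at percentile 39.7 of random lists matched on expression.

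Of 12312 measured genes, 486 were at least 2-fold higher in the knockdown library and 647 were at least 2-fold lower. Within 1.5-fold lay 75.8% of measured genes. By total counts alone the split turned, with 629 genes higher and 549 lower, because that scaling moved the median log2 ratio of all genes from 0.01 to 0.11. The share of 2-fold genes that were higher was 42.9% in the main scaling, 53.4% by total counts and 28.8% with FPKM and a pseudocount of 1. The lowest decile of expression had 208 genes higher and 162 lower, whereas the highest decile had 10 higher and 41 lower. Median log2 ratios were 0.16 and -0.13 in these deciles.

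**Figure D1:**
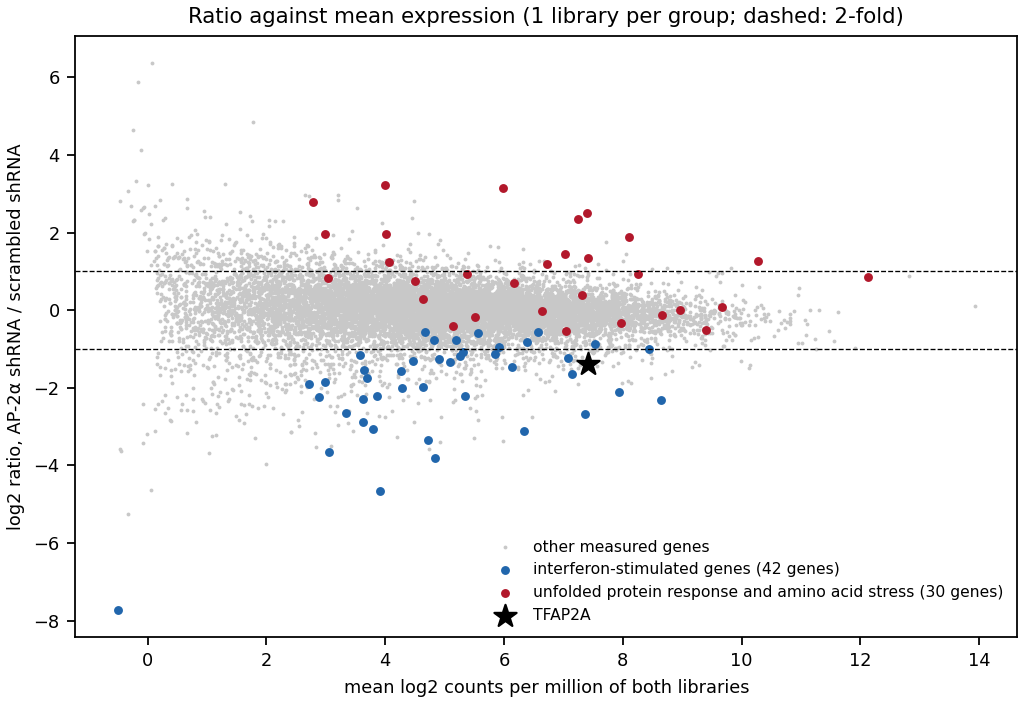
Log2 ratio of the AP-2α shRNA library over the scrambled shRNA library (y axis) against the mean log2 CPM of both libraries (x axis), 1 point per measured gene, with 2-fold marked by dashed lines. The 42 interferon-stimulated genes (blue) all lie below 0, 13 of the 30 unfolded protein response and amino acid stress genes (red) lie at or above the upper line, and TFAP2A is the star.

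Among genes with a symbol and enough counts, those with the largest ratios included members of several of the gene lists. The most strongly lower genes included the interferon-induced IFI44L, MX2, OAS2, IFI44, OAS1 and IFITM1. Also among these 15 genes were WNT7A, a WNT ligand (11.97-fold lower), the collagen chain COL8A1 (11.4-fold), the neutrophil-type calcium-binding protein S100A9 (11.3-fold), the chemokine CXCL1 (10.5-fold), SERPINA1, which encodes alpha-1 antitrypsin (9.68-fold), and the elastase inhibitor PI3 (8.95-fold). TSPAN18 was 15.7-fold lower, TMEM171 12.9-fold lower and DOCK10 9.20-fold lower. On the other side, HSPB8, a small heat shock protein that acts with BAG3, was 28.9-fold higher (interval 16.4 to 56.3), from 12 to 452 counts. CHAC1, a glutathione-degrading enzyme, was 9.36-fold higher, the asparagine synthetase ASNS 8.96-fold and the pseudokinase TRIB3 5.70-fold. DDIT3, which encodes the transcription factor CHOP, was 6.98-fold higher. GPNMB (9.61-fold), KIF1A (7.86-fold), ANKRD1 (7.85-fold), NPAS1 (7.77-fold), the BH3-only gene HRK (7.32-fold), ADM2 (7.04-fold), TSC22D3 (6.21-fold), IRF8 (5.83-fold), FBLL1 (5.37-fold) and ARHGAP42 (5.32-fold) completed the 15 such genes on the higher side. A pair of features without a symbol had larger ratios, 82.4-fold (interval 22.5 to 685) and 58.7-fold higher (interval 15.96 to 489), each from 2 counts in the control library. Several of these started from few counts: 11 for HRK, 15 for GPNMB and 16 for ARHGAP42 in the control library.

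**Figure D2:**
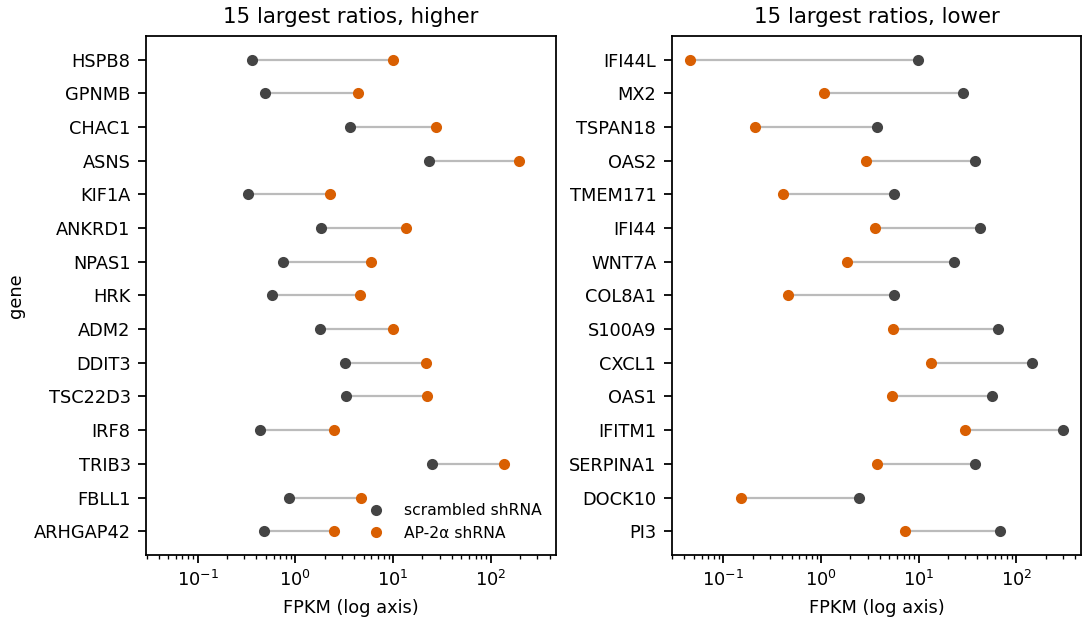
Deposited FPKM (x axis, log scale) of the 15 genes with a symbol and the largest ratio in each direction, with the scrambled shRNA library in grey and the AP-2α shRNA library in orange, 1 library each. ASNS went from 23.4 to 196 and CXCL1 from 146 to 13.5.

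Interferon-stimulated genes were lower in the knockdown library throughout the list. All 42 measured members had a lower level, 33 of them by at least 2-fold, none was higher, and the median was 3.22-fold lower (interval 2.39 to 4.59). Under each of 6 other scalings or units all 42 were again lower. The member nearest to no difference had a log2 ratio of -0.56. Total counts, DESeq2 size factors and upper-quartile scaling shift all genes alike by less than that, so they could not turn a sign. The median FPKM of the list was 27.8 in the control library and 7.72 in the knockdown library. IFI44L had 161 counts in the control and 1 in the knockdown library, a ratio of 0.00476 with an interval of 0.000120 to 0.0269. MX2, a GTPase with antiviral activity, was 25.2-fold lower (FPKM 28.7 and 1.08). OAS2, a sensor of double-stranded RNA, was 14.0-fold lower and IFI44 12.6-fold lower. This median lay below all 10000 random lists of the same size matched on expression. Genes of MHC class I antigen processing were lower to a smaller extent. Of 16 measured, 15 were lower, 2 of them by at least 2-fold (1 by total counts), with a median of 1.57-fold (interval 1.29 to 1.78). The immunoproteasome subunits PSMB9 and PSMB10 were 2.25-fold and 2.03-fold lower, the peptide transporter subunit TAP2 1.83-fold and the trimming peptidase ERAP1 1.78-fold. The lists share 3 genes, and without these the antigen processing median was 1.49-fold lower over 13 genes. The median of the whole antigen processing list also lay below all 10000 random lists.

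Inflammatory cytokine and NF-kB genes were also lower. Of 27 measured, 23 were lower, 12 of them by at least 2-fold, and none was at least 2-fold higher. The median was 1.76-fold lower (interval 1.34 to 2.61). CXCL1 was 10.5-fold lower (FPKM 146 and 13.5) and CXCL6, another neutrophil chemokine, 9.03-fold lower. TNF and IL1B, the canonical inflammatory cytokines, were 7.17-fold and 5.33-fold lower from low levels of 66 and 98 counts. Immediate early genes were lower in 22 of 26 cases, 6 by at least 2-fold, with a median of 1.54-fold (interval 1.28 to 1.86), while ATF3 and KLF10 were 2.37-fold and 2.41-fold higher. EGR1 was 2.74-fold lower, MYC 2.64-fold, the ERK phosphatase DUSP6 2.44-fold and CCN2 2.19-fold. Of 12 measured EGFR family members and ligands, 10 were lower, 3 by at least 2-fold. EPGN, which encodes the ligand epigen, was 24.8-fold lower (interval 10.3 to 78.1) from 95 to 5 counts. NRG2, EREG and HBEGF were 3.60-fold, 2.21-fold and 1.59-fold lower. The percentile of this list's median was 0.86, and those of the preceding pair were below all 10000 random lists.

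Epithelial genes were lower as groups, with many members little different. Of 26 measured junction genes, 22 were lower and 4 were lower by at least 2-fold, with a median of 1.44-fold (interval 1.16 to 1.74). On the higher side, DSP, picked after its values were seen, was 1.99-fold higher and passed 2-fold by total counts and upper-quartile scaling. PKP2, a desmosomal plakophilin, was 2.98-fold lower, CDH1, which encodes E-cadherin, 2.95-fold (FPKM 23.2 and 7.36), the tight junction gene CLDN1 2.68-fold and TJP3 2.17-fold. Of 19 urothelial differentiation genes, 13 were lower, 3 by at least 2-fold, and none was at least 2-fold higher. The median log2 ratio was -0.50, and its interval of -0.89 to 0.06 included 0. GRHL3, a transcription factor of the umbrella cell layer, was 6.05-fold lower, the pioneer factor FOXA1 2.87-fold, the uroplakin UPK1B 2.56-fold (FPKM 90.6 and 39.1) and CLDN4 1.91-fold. Of 23 basal and squamous genes, 17 were lower, 6 by at least 2-fold, and 1 was at least 2-fold higher. The median log2 ratio was -0.50, with an interval below 0 throughout. IVL, which encodes involucrin, was the gene past 2-fold on the higher side, at 2.23-fold. The measured keratins of the list split. KRT5, KRT6A, KRT16 and KRT17 were 1.03-fold, 1.18-fold, 1.29-fold and 1.29-fold higher, while KRT14 was 1.42-fold and KRT15 3.70-fold lower. S100A9 and PI3 were 11.3-fold and 8.95-fold lower, and the hyaluronan receptor CD44 was 2.56-fold lower. Medians of these 3 lists lay at percentile 0.03 or lower.

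The mesenchymal list had no common direction. Of 19 measured members, 10 were higher and 9 lower (9 and 10 with FPKM or the authors' scaled counts), and the median lay at percentile 65.5. The intermediate filament gene VIM was 3.70-fold lower (FPKM 176 and 46.5) and the matrix protein SPARC 3.11-fold lower. CDH2, which encodes N-cadherin, was 2.92-fold higher and the transcription factor SNAI2 2.83-fold higher. Genes of matrix proteolysis went both ways, with the larger ratios on the lower side. Among 22 proteases and inhibitors, 6 were at least 2-fold lower and none at least 2-fold higher, and the median log2 ratio was -0.36 (interval -1.02 to 0.34). MMP9, a gelatinase, was 7.13-fold lower (FPKM 43.1 and 5.90), SERPINB2 4.24-fold and SERPINB5 2.22-fold, and ADAMTS1 had FPKM values of 18.5 and 6.89. The protease median lay at percentile 0.09, with 12 members lower and 10 higher. Among 18 integrins and laminins, 16 were lower, 4 by at least 2-fold, with a median of 1.36-fold (interval 1.14 to 1.69). ITGB8 was 3.22-fold lower, while ITGA5 (2.03-fold), LAMA4 (2.01-fold) and ITGA2 (FPKM 20.9 and 9.90) lay close to the 2-fold rule, and by total counts 1 member reached it. The percentile of this list was 0.08.

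Among developmental signalling pathways, the WNT and NOTCH lists had lower medians, and the TGF-beta and BMP list lay within the range of random lists. Of 26 measured WNT pathway genes, 21 were lower, 7 by at least 2-fold, against 1, the receptor FZD7, that was 2.21-fold higher. By total counts 4 were at least 2-fold lower. WNT7A went from 1780 to 194 counts. The ligands WNT5A and WNT4 were 3.81-fold and 3.64-fold lower, and the secreted antagonist SFRP1 was 2.34-fold lower. The WNT median was 1.30-fold lower (interval 1.07 to 1.76), at percentile 0.02. Of 15 NOTCH pathway genes, 13 were lower, 3 by at least 2-fold, and the median was 1.76-fold lower (interval 1.04 to 1.86). The receptors NOTCH4 and NOTCH3 were 3.06-fold and 2.63-fold lower, the effector HES2 2.58-fold and the ligand DLL1 1.86-fold. HEY1, a further effector, was 6.35-fold higher. This median lay below all 10000 random lists. The TGF-beta and BMP list had its median at percentile 17.7, with 13 of 23 genes lower. Its members FST (3.68-fold), LTBP2 (3.12-fold), TGFBI (2.72-fold) and BAMBI (2.56-fold) were lower, while SMAD6 was 2.28-fold higher.

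Glycolytic and hypoxia-responsive genes were lower. Of 19 measured glycolysis genes, 18 were lower, with a median of 1.65-fold (interval 1.42 to 1.79), although 2 reached 2-fold in the main scaling, 1 by total counts, and 4 by DESeq2 size factors, FPKM or the authors' scaled counts. LDHA, which encodes the lactate dehydrogenase A subunit, was 2.66-fold lower (FPKM 2179 and 768). The hexokinase HK2 was 2.14-fold lower, and PFKP (FPKM 205 and 101) and PKM (FPKM 1380 and 677) lay just under the 2-fold rule. Of 26 hypoxia genes, 20 were lower, 8 by at least 2-fold, with a median of 1.55-fold (interval 1.12 to 2.14). ANGPTL4 was 6.76-fold lower, the lysyl oxidase LOXL2 3.70-fold and the HIF prolyl hydroxylase EGLN3 2.99-fold. The median of the glycolysis list lay below all 10000 random lists and that of the hypoxia list at percentile 0.01. The 2 lists share 5 measured genes. Without them the hypoxia median was 1.55-fold lower over 21 genes and the glycolysis median 1.66-fold lower over 14. Oxidative phosphorylation genes encoded in the nucleus did not follow: none of 42 reached 2-fold and the median lay at percentile 24.9.

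Genes of the unfolded protein response and amino acid stress list were higher in the knockdown library. Of 30 measured, 23 were higher, 13 of them by at least 2-fold, none was at least 2-fold lower, and the median was 1.86-fold higher (interval 1.23 to 2.55). The 4 with the largest ratios were CHAC1 (FPKM 3.59 and 27.6), ASNS (23.4 and 196), DDIT3 (3.23 and 21.6) and TRIB3 (25.3 and 137). The median of the list lay above all 10000 random lists. Among members picked after their values were seen, the serine synthesis enzymes PSAT1 and PHGDH were 5.11-fold and 3.71-fold higher and the cystine transporter SLC7A11 3.91-fold higher, whereas the chaperones HSP90B1 and PDIA4 were 1.25-fold and 1.44-fold lower. The histone list was also higher, with 6 of 13 measured genes at least 2-fold higher and none at least 2-fold lower. With FPKM, 4 were at least 2-fold higher. The median was 1.69-fold higher, above all 10000 random lists, although its log2 interval of -0.32 to 1.49 included 0. HIST2H2AA3 (3.18-fold), H4C8 (2.88-fold), H2AC6 (2.81-fold) and H2BC21 (2.53-fold) were higher from low FPKM values of 1.54, 1.76, 9.57 and 4.44. Histone genes share sequence with near-identical copies, so their separate counts are uncertain. The 3 measured metallothioneins, MT2A, MT1X and MT1F, which bind zinc and copper and resemble each other in sequence, were 1.93-fold, 1.55-fold and 1.49-fold higher, and their median lay at percentile 97.8.

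Other stress and metabolic lists were mixed. Of 17 NRF2 target genes, 10 were lower. Their median log2 ratio was -0.33 but their mean was 0.02, so the sign depended on the summary. The median lay at percentile 0.845. By at least 1.5-fold, 4 members were higher and 3 lower. HMOX1 and SLC7A11, the members at least 2-fold higher, also belong to other lists, as does NQO1 on the lower side. FTH1, a further member, was 1.85-fold higher. ABCC3 was 2.79-fold lower, NQO1 1.60-fold, ME1 1.52-fold and TKT 1.43-fold. Of 17 xenobiotic and retinoid response genes, 10 were lower, 5 by at least 2-fold, with a median at percentile 0.125. The vitamin D hydroxylase CYP24A1 was 3.61-fold lower, the retinol transporter STRA6 3.15-fold, UGT1A6 2.65-fold and CRABP2 2.46-fold. UGT1A6 shares exons with the other genes of its cluster. Heat shock genes had a median at percentile 23.4. Besides HSPB8, the list held CRYAB, with 44 and 115 counts and a ratio at the 2-fold rule, and the constitutive chaperone HSPA8, 2.02-fold lower. Cholesterol synthesis genes had a median at percentile 18.9, with the sterol carrier STARD4 2.63-fold lower. Of the 24 measured genes reported elsewhere as AP-2α targets, 21 lay within 2-fold. By total counts 2 were at least 2-fold higher and 1 lower. HMOX1, the inducible heme oxygenase, was 2.97-fold higher, while CDH1 was 2.95-fold and PLAU, which encodes urokinase, 2.03-fold lower. The median of this list lay at percentile 7.93. The list was not split by reported direction of regulation, so members moving opposite ways could cancel in that median.

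Proliferation genes lay mostly within 2-fold. None of 31 genes of G2 and mitosis reached 2-fold, and the interval of the median log2 ratio, -0.17 to 0.14, included 0, at percentile 88.7. Of 29 genes of the G1 to S transition and replication, 1 reached 2-fold: CCND1, which encodes cyclin D1, was 3.68-fold lower (FPKM 160 and 42.2). On the higher side, MCM6, picked after its values were seen, lay just under 2-fold and passed it by total counts and upper-quartile scaling. The list had 15 genes higher and 14 lower, against 22 and 7 by total counts and 13 and 16 with FPKM, and its median lay at percentile 80.3. Of 27 p53 target genes, 1 reached 2-fold, CCNG1, which was 2.36-fold lower, and the median lay at percentile 31.7. None of 62 cytosolic ribosomal protein genes and none of 25 housekeeping genes reached 2-fold, although 1 housekeeping gene did with FPKM. The ribosomal median was 1.16-fold lower, at percentile 3.98, and the housekeeping median lay at percentile 19.4. Markers of other cell types were mostly unmeasured, with 3 of 12 fibroblast, 5 of 14 leukocyte, 4 of 9 endothelial and 5 of 10 smooth muscle genes passing the filter. Among them CSF1R was 5.16-fold and ESAM 3.07-fold higher, while LAPTM5 was 4.73-fold and CDH5 5.65-fold lower. The smooth muscle median lay at percentile 97.7. It lay inside the central 95% of random lists under 3 of the 5 other settings that can move a percentile, which were FPKM with either pseudocount and removal of a length trend. Its members ACTA2, SYNM, TAGLN and MYLK were 1.86-fold, 1.41-fold, 1.41-fold and 1.16-fold higher, the last with an interval of 0.983 to 1.36, and the remaining member, SMTN, was 1.39-fold lower. The medians of the leukocyte, endothelial and fibroblast markers lay at percentiles 11.5, 3.71 and 50.3.

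**Figure D3:**
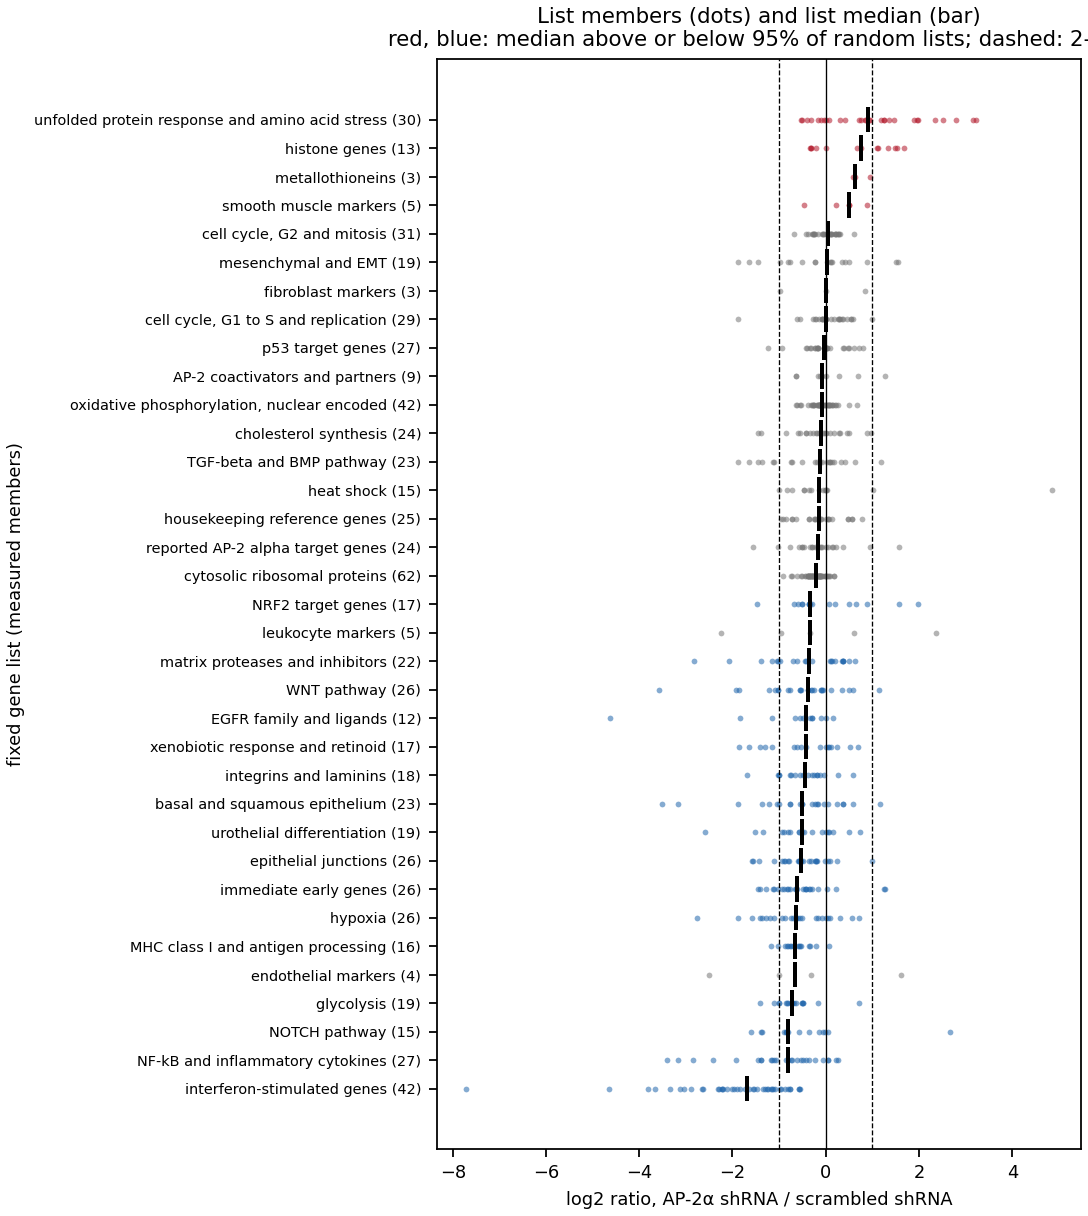
Log2 ratio of the AP-2α shRNA library over the scrambled shRNA library (x axis) for each measured member (dot) of 35 gene lists (y axis, with the number of measured members), with the list median as a bar. Red and blue mark medians above and below the central 95% of random lists matched on expression, and dashed lines mark 2-fold. The interferon-stimulated list has the lowest median, -1.69, and the unfolded protein response and amino acid stress list the highest, 0.90.

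In all, 16 of the 35 lists with at least 3 measured members had medians below the central 95% of random lists and 4 had medians above it, where 1.75 lists would fall outside by chance if genes varied independently. Genes of a pathway vary together and lists share members, so these percentiles describe the 2 libraries and are not tests of the knockdown.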

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

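No replicate could be left out and no paired analysis was possible because each group holds 1 library and the labels share no replicate numbers. The authors' scaled counts, the removal of trends on expression, GC content and length, and the settings for the expression deciles were chosen after the data were seen. DESeq2 size factors, upper-quartile scaling and the authors' scaled counts left the TFAP2A ratio inside its counting interval. The ratio was 0.382 in the main scaling, 0.410 by total counts, 0.324 from FPKM with a pseudocount of 0.1 and 0.327 with a pseudocount of 1, each a lower level. The number of genes at least 2-fold higher and lower depended on filter, rule and unit. Against 486 higher and 647 lower, the counts were 1790 and 1960 with no filter, 203 and 414 with at least 200 counts and an FPKM of 5, 1433 and 1542 at 1.5-fold, and 117 and 243 at 3-fold. With the whole counting interval beyond 2-fold, 187 were higher and 435 lower, and with FPKM and a pseudocount of 1, 206 were higher and 509 lower. Lower genes outnumbered higher ones in each of these, and higher ones did by total counts (629 and 549). Of the 1133 main genes, 1035 were also at least 2-fold by total counts, 1126 by DESeq2 size factors, 1000 from FPKM with a pseudocount of 0.1 and 666 with a pseudocount of 1. A pseudocount of 1 pulls the ratios of low genes toward 1 by construction. For the medians of lists, 378 alternative values stayed within the binomial interval of the main median with no change of sign in a list outside the random range. NRF2 targets changed sign within their interval, with a mean of 0.0209 against a median of -0.33. The 5 values outside their interval were heat shock genes, whose mean was 0.10; G2 and mitosis genes at 0.15 and ribosomal protein genes at -0.12 by total counts; and, with trends on expression, GC content and length removed, glycolysis genes at -0.51 and ribosomal protein genes at -0.0708. The causes were not tested. Of the 20 lists outside the central 95% of random lists, 19 were also outside in each of the 5 settings that can move a percentile (FPKM with either pseudocount, the authors' scaled counts and both trend removals), and the exception was smooth muscle markers; endothelial markers were outside with FPKM and a pseudocount of 1 alone. Total counts, DESeq2 size factors and upper-quartile scaling shift all log2 ratios alike and cannot move a percentile, and the authors' scaled counts are nearly such a shift. Counts of members past 2-fold also moved by 1 or 2 genes with scaling or unit in other lists, among them heat shock, cholesterol, metallothionein, TGF-beta and BMP, mesenchymal and endothelial genes. For the named genes other than TFAP2A, 606 alternative ratios lay in the counting interval and 108 outside it, and no gene with a ratio of at least 2-fold changed direction. Depth limits the low genes: ratios resting on 11 to 27 control counts, such as HRK, have intervals spanning several-fold. The top decile median minus the bottom one was -0.29, and -0.25 and -0.22 from FPKM with pseudocounts of 0.1 and 1; library scalings cannot move it.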

Other observations

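Gene families not fixed as lists were also compared between the 2 libraries. These families and all tests here, apart from the prediction on further ATF4 targets, were chosen after the gene table was seen. The collagen and interleukin families share members with the fixed lists, so their counts partly repeat results above. Cytosolic aminoacyl-tRNA synthetases split: 12 of 20 were higher and 8 lower. CARS1 was 2.39-fold, WARS1 2.30-fold, YARS1 2.21-fold and MARS1 2.12-fold higher, while LARS1 differed by 1.05-fold. The median log2 ratio was 0.44 with an interval of -0.08 to 0.99, at percentile 100 of random lists. Collagen chains were lower in 17 of 20 cases, with a median of 1.65-fold (log2 interval -1.27 to -0.24, percentile 0). COL1A1, COL5A1, COL6A1 and COL6A2 among them are also in the mesenchymal list, and COL17A1 is in the basal list. COL12A1 was 5.28-fold, COL13A1 4.41-fold and COL16A1 4.20-fold lower, whereas COL4A3 and COL4A4 were 3.64-fold and 2.39-fold higher. Of 35 genes picked by an IL symbol, mostly interleukins and their receptors, 29 were lower, 13 by at least 2-fold. IL7R was 5.96-fold and the decoy receptor IL1R2 4.28-fold lower. Several of the 35, such as IL1A, IL1B, IL6, IL18 and IL32, are also in the NF-kB list. Mitochondrial ribosomal proteins stayed within 2-fold in 68 of 68 cases.

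Several genes used as references were not level. ACTB was 1.95-fold lower (FPKM 2798 and 1400), PPIA 1.89-fold lower and GAPDH 1.79-fold lower, while TFRC was 1.70-fold and TBP 1.48-fold higher. FTH1, the ferritin heavy chain, which has many processed pseudogenes, was 1.85-fold higher at an FPKM of 6288 and 11210.

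All 42 measured interferon-stimulated genes were lower in the knockdown library. Over measured genes, the ratio had only weak rank correlations with expression level (Spearman -0.132), GC content (-0.102) and length (-0.028). Trends this weak are argued against as the whole cause. Removing them left the median log2 ratio at -1.78 (interval -2.18 to -1.27) against -1.69 before, but such weak trends could have moved it only little. An interferon response already running in the control culture, to the virus, the scrambled shRNA or culture conditions, remains open. Lentivirus and puromycin were common to both cultures, so a response to the virus would have to differ in extent between them. The list was well expressed in the control library, with a median FPKM of 27.8, which allows such a response. The 17 interferon genes examined summed to 30 counts in the control and 12 in the knockdown library, too few to show local interferon transcription, but interferon made earlier would no longer be seen as RNA. With 1 library per group, that response and an effect of AP-2α loss cannot be told apart.

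The amino acid stress genes were higher. After trends were removed, the 24 members outside a set of endoplasmic reticulum chaperones had a median log2 ratio of 1.22 (interval 0.73 to 1.89), against 1.22 before. The weakness of these trends over all measured genes argues against them as the whole cause, and their removal could have changed only little. The 13 chaperone genes had a median of -0.14 (interval -0.32 to 0.15) and so were not higher as a set, although MANF among them was 1.48-fold higher. That set was chosen after the gene table was seen and holds members of the fixed list, such as HSPA5, HSP90B1 and PDIA4. Leaving its members out raised the list median from 0.90 to 1.22. The split therefore cannot decide on a general stress of the endoplasmic reticulum. With the co-chaperone gene DNAJB9 moved from the 24 to that set, the medians were -0.08 over 14 genes (interval -0.32 to 0.30) and 1.23 over the other 23 after trends were removed. Other genes known to respond to such stress, counted here among the 24, were higher: XBP1 2.27-fold, PPP1R15A 2.55-fold, DNAJB9 1.79-fold and HERPUD1 1.69-fold. A stress of the endoplasmic reticulum stays open. A candidate explanation is a programme of ATF4, a transcription factor induced by amino acid shortage among other stresses. It was predicted after the fixed list was seen to be higher, but before the values of further ATF4 targets were looked at. The 22 further ATF4 target genes outside the fixed list had a median of 0.62 (interval 0.37 to 0.97), and 19 were higher, among them SLC1A4 (2.79-fold) and ALDH1L2 (2.54-fold). They do not tell which stress would have induced ATF4. Whether the higher levels follow AP-2α loss or a difference in medium or density between the 2 cultures was not tested.

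Protein-coding ZNF genes, which encode zinc finger proteins, were higher in 300 of 351 cases, 58 by at least 2-fold, with a median of 1.36-fold. Removing trends on expression, GC content and length lowered the median log2 ratio from 0.44 to 0.37 (interval 0.32 to 0.43), so these trends may account for a part and were argued against as the whole. On chromosome 19, where 166 of them lie, the ZNF genes had a median of 0.67 (interval 0.56 to 0.86). The other 749 genes of that chromosome had a median of 0.00923 (interval -0.03 to 0.04), which argues against a gain of the whole chromosome. Genes beside the ZNF genes were not examined apart, so a gain of parts of the chromosome was not tested. The 185 ZNF genes elsewhere had a median of 0.29. Reads shared between these related genes and an effect of AP-2α loss stay open and were not tested.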
